A study of Homo sapiens with 5 samples.

How the data were processed

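Gene expression was measured on Illumina bead arrays in LNCaP cells, an established human prostate cancer line. Per the labels' protocols, cells received retroviral vectors carrying short hairpin RNAs (shRNAs) made in 293T packaging cells, and total RNA was taken 3 days after infection. There was 1 array for a non-targeting control vector, 2 for ETV1 (shRNAs 1 and 5) and 2 for JMJD2A (shRNAs 3 and 5). JMJD2A is an older symbol of KDM4A, which is used for its mRNA. The arrays of a target carry different hairpins, so each array comes from cells infected with its own vector. The labels do not say whether these infections were made at the same time.

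The values used are the deposited value table of 47323 probes per array. They are log2 signals that the authors had quantile normalized across the 5 arrays, as seen from the values, since the sorted values of all arrays coincide (range 6.18 to 14.19, median 6.59). The software and the background correction are not given in the sources used here. The lowest values lie well above 0 on the log2 scale, so background is part of them and folds of weakly expressed genes are compressed. A second deposited table, of signals before normalization with detection p-values, was not used here, because its 5 signal columns carry names that match no sample label.

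Before the data were examined, the plan was normexp background correction of the unnormalized signals, quantile normalization and a filter on detection p, with normexp at an offset of 50 where no detection p could be used. Because those signals were not used and the deposited values were already normalized, limma was run on the deposited log2 values instead. A background floor replaced the detection filter. The mode of the signals was 6.51, the SD on its low side 0.072, and the 0.99 quantile of that normal distribution gave a floor of 6.68. A probe was tested if it exceeded the floor on at least 1 of 5 arrays, which kept 22600 probes, 16110 of them above it on all 5 arrays. The use of the deposited values and the floor were chosen after the data were seen.

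Probes were assigned to genes through the platform annotation, which gave a single symbol to 30113 probes, several to 8 and none to 17202. Symbols were updated by Entrez ID with the RefSeq gene table of GRCh38.p14, in which 30074 probes matched. The tested probes included 16848 with a symbol, for 12323 genes, of which 3482 had more than 1 probe. A gene was represented by its tested probe with the highest mean.

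Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) from 3 group means over all 5 arrays, for ETV1 shRNA against control, JMJD2A shRNA against control, and ETV1 against JMJD2A shRNA. The fit had 2 residual degrees of freedom, a prior SD of 0.132 and 4.78 prior degrees of freedom. The lone control array was assumed to vary like the shRNA arrays, whose spread is that between different hairpins of a target. P-values were two-sided and Benjamini-Hochberg adjusted over 22600 probes, with a threshold of 0.05. Errors are limma standard errors (SE) unless a standard deviation (SD) is named. The p-values measure only the spread between these samples. The number of arrays limits the precision.

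Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe per gene, with adjustment over 60 tests (20 lists in 3 comparisons). The lists were fixed before the values were read, and 19 of them are described. These held YAP/TAZ-TEAD targets, Hippo pathway components, invasion and ETS-associated genes, MAPK output genes, histone lysine demethylases, p53 targets, G2/M and mitosis genes, DNA replication genes, interferon-stimulated genes, ER stress and integrated stress response genes, cholesterol synthesis genes, fatty acid synthesis genes, hypoxia and glycolysis genes, epithelial genes, mesenchymal and fibroblast markers, neuroendocrine genes, MYC and ribosome biogenesis genes, NF-kB targets and housekeeping genes. A list of 6 neuronal and fetal genes of 293T cells had 2 members above the floor on any array, NEFL and IGF2BP1, neither beyond 6.72, and was not tested.

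Named genes followed a rule set in advance. It took ETV1, KDM4A and YAP1, up to 10 genes per direction and comparison that passed the threshold with both shRNAs moving alike, and up to 4 members of each list with the largest differences. Where fewer than 10 passed, it added the genes with the largest value of the smaller of the hairpins' differences, given as values. Genes outside the rule are stated to be so.

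The shared control was handled by 100 simulations of unchanged probes with the fitted spread. The procedure was tested on simulated data with 50 changed probes per fold size among 22600, in 20 draws. Each draw held 200 changed probes, which makes the adjusted threshold easier to pass than where few probes change. The simulated arrays were independent and of equal spread, which the real arrays did not meet, so the rates may differ for them. Alternatives were no filter, the floor required on all 5 arrays, an intensity trend in eBayes, only the compared groups in the fit, averaged probes of a gene, each array left out in turn, camera with an estimated correlation, fry, subtraction of the background mode with an offset of 16, and normexp with an offset of 50 on the unlogged deposited values. The subtraction, the normexp step applied to the deposited values and the floor on all 5 arrays were added after the data were seen. Alternatives set beforehand that need the unnormalized signals or detection p (no background correction, median scaling, detection filters) were not run, and the deposited value table, first meant as an alternative, is the main source. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No probe sequences or genome were used.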

Results

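Genome-wide mRNA signals were compared in LNCaP cells, an established line from a metastasis of human prostate cancer, after infection with shRNAs against ETV1 or JMJD2A (KDM4A). ETV1 is an ETS-family transcription factor and KDM4A a histone lysine demethylase. The groups were 1 array with a non-targeting control vector, 2 arrays with different ETV1 shRNAs and 2 arrays with different JMJD2A shRNAs. On each array, 18673 of 47323 probes (39.5%) lay above the background floor of 6.68. The SD of the probe differences was lowest between ETV1 shRNA 1 and JMJD2A shRNA 3, at 0.18. It was 0.25 between the ETV1 arrays, 0.23 between the JMJD2A arrays, and 0.24 to 0.29 between the control and the others.

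The probes of the targeted genes read close to background, and 1 probe each does not show how abundant these mRNAs were. ETV1 had 1 probe, with log2 signals of 6.67 in the control, 6.47 and 6.47 with the ETV1 shRNAs, and 6.62 and 6.75 with the JMJD2A shRNAs. It exceeded the floor only on the array of JMJD2A shRNA 5, and its difference from the control with ETV1 shRNA was -0.20 ± 0.14 (SE), with a limma adjusted p of 0.798. KDM4A, also with 1 probe, had 6.91 in the control, 6.76 and 6.57 with JMJD2A shRNAs 3 and 5, and 7.08 and 6.80 with ETV1 shRNAs 1 and 5. Its difference was -0.25 ± 0.18 with JMJD2A shRNA (limma adjusted p = 0.882) and 0.02 ± 0.18 with ETV1 shRNA (adjusted p = 0.987). With the background mode subtracted the differences were -0.74 for ETV1 and -0.82 for KDM4A, each with its own shRNA, and neither passed. At these signals the arrays neither show nor exclude a knockdown of either mRNA, so groups are named by the hairpin on the label. A group called a knockdown is one given that hairpin, without a measured loss of the mRNA.

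The comparison of ETV1 shRNA with the control asked which mRNAs changed when ETV1 was targeted. RIPOR2, which encodes an inhibitor of RHOA signalling, fell by 2.43 ± 0.15 on the log2 scale (SE, n = 2 against 1 array), a 5.38-fold lower signal. Its log2 signal was 9.63 in the control, 7.18 and 7.23 with the ETV1 shRNAs (mean 7.20, SD 0.04), and 9.03 and 9.24 with the JMJD2A shRNAs (mean 9.14, SD 0.15). MMP7, a secreted matrix metalloproteinase of the invasion list, read 7.63 in the control and lay under the floor with both ETV1 shRNAs (6.58 and 6.51), so the signal of this probe was at least 1.93-fold lower. Its difference of -1.08 ± 0.18 had a limma adjusted p of 0.539, and the other MMP7 probe gave a smaller difference of -0.49. Among genes given as values, the differences were -1.24 ± 0.28 for the adhesion receptor ADGRG6, -1.12 ± 0.17 for CIAO2A of iron-sulfur cluster assembly (its other probe gave -1.07), -1.09 ± 0.22 for the vesicle release factor CADPS2, and -0.91 ± 0.16 for the kinetochore gene CENPN. Higher values included 1.02 ± 0.17 for the lysosomal peptidase DPP7, whose 3 other probes also lay higher, 0.94 ± 0.18 for the mitochondrial peptidase MIPEP, and 0.89 ± 0.17 for the reticulon RTN1, whose 2 other probes also lay higher. TRIM49D1 (1.06 ± 0.15) and TRIM48 (0.97 ± 0.22) belong to a family of near-identical copies, so their identity is uncertain.

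With limma, 1 of 22600 probes passed, the RIPOR2 probe (adjusted p = 0.0308). At an unadjusted p under 0.05 there were 1871 probes, 964 higher and 907 lower, against 1130 expected by chance. On simulated data for this comparison, 32.6% of probes changed 2-fold and 90.4% of those changed 3-fold were recovered, and 7.45 unchanged probes passed on average. These rates hold for 200 changed probes on independent arrays of equal spread, and would be lower where few probes change. RIPOR2 rests on a single probe, and its call was lost without the dim-probe filter (adjusted p = 0.20), with the floor required on all 5 arrays (0.0544), without the array of ETV1 shRNA 1 (0.369) and without that of ETV1 shRNA 5 (0.357), in a range of 3.21e-05 to 0.369 over the alternatives. The difference itself stayed between -2.40 and -2.45 in these settings. With an intensity trend 3 probes passed, RIPOR2, MMP7 and TLL1 (both at an adjusted p of 0.0437), where TLL1, a metalloproteinase gene with a difference of -0.85, lies outside the naming rule and was chosen after its values were seen.

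**Figure D1:**
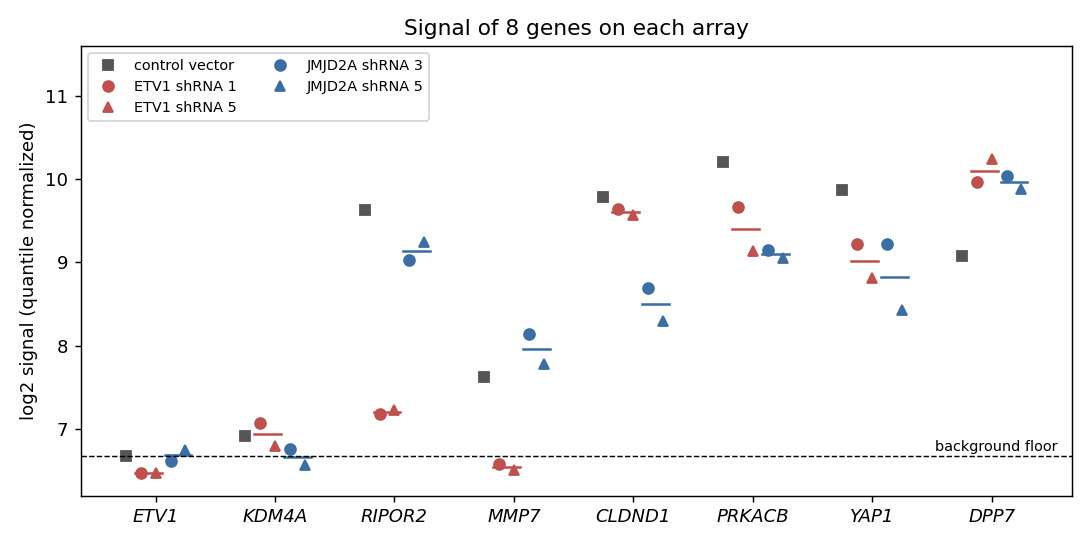
Log2 signal of 8 genes (vertical axis) on each of the 5 arrays (control vector, ETV1 shRNAs 1 and 5, JMJD2A shRNAs 3 and 5), with 1 point per array, bars at the means of each target's arrays and a dashed line at the background floor of 6.68. RIPOR2 read 7.18 and 7.23 with the ETV1 shRNAs and 9.03 to 9.63 on the other arrays.

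The G2/M and mitosis list had a median under 0 with ETV1 shRNA, in a call that depended on the set test and on 1 array. Of the 26 G2/M and mitosis genes measured, 19 lay lower and 3 higher with both hairpins, and the list's median was -0.25 (-0.31 with shRNA 1 and -0.17 with shRNA 5). JMJD2A shRNA 3, the array closest to ETV1 shRNA 1, had a similar median of -0.25. Both hairpins of a target are set against the same control array, which by itself makes their differences agree in sign. Across all probes the differences with the ETV1 hairpins had r of 0.567, where simulations of independent unchanged arrays gave 0.501. Counts of members with both hairpins, for each list and target, are therefore no replication across hairpins. The spindle genes HMMR (-0.64 ± 0.26) and DLGAP5 (-0.61 ± 0.22), the mitotic kinase NEK2 (-0.59 ± 0.22) and the topoisomerase TOP2A (-0.54 ± 0.32) had the largest differences. With 1 ETV1 array left out HMMR ranged from -0.96 to -0.32 and TOP2A from -0.82 to -0.26. In all 0 members passed in limma over all probes or adjusted over the list alone, with 6 at an unadjusted p under 0.05. The list fell in limma's camera test (adjusted p = 0.00498). It did not pass with a correlation estimated from these arrays, 0.49, where the value was adjusted p = 0.965 with an estimated correlation, or with fry (adjusted p = 0.977), and without the array of ETV1 shRNA 1 it had an adjusted p of 0.430.

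Epithelial genes held some of the larger values among the 18 other lists described, none of which passed with ETV1 shRNA (camera adjusted p from 0.459 to 0.986). Epithelial genes had 6 of 12 higher and 3 lower with both hairpins, the sense in which members are counted for each list with an shRNA against the control (median 0.055), with KRT18 at 0.82 ± 0.15 and KRT8 at 0.53 ± 0.18, keratins of simple epithelia, and the junction gene TJP1 at -0.43 ± 0.15. Across the 19 lists described 0 members passed in limma over all probes. The members that passed when adjusted over the list alone were MMP7 (adjusted p = 0.00797), KRT18 (0.0125) and the sterol reductase TM7SF2 (0.0442).

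The growth and metabolic lists had medians under 0 when the ETV1 hairpins were averaged, but the cholesterol synthesis list had 0.029 and 0.089 with shRNAs 1 and 5 taken singly, and the fatty acid list 0.036 and -0.23. DNA replication genes had 12 of 28 lower and 5 higher with both hairpins (median -0.066), including the primase PRIM1 (-0.69 ± 0.19) and the clamp loader RFC4 (-0.49 ± 0.21). Hypoxia and glycolysis genes had 13 of 22 lower and 5 higher (median -0.14), with the mitophagy gene BNIP3 at -0.58 ± 0.27 and hexokinase HK2 at -0.55 ± 0.25. ER stress genes had 10 of 16 lower and 2 higher (median -0.10), with the mTORC1 inhibitor DDIT4 at -0.51 ± 0.20 and asparagine synthetase ASNS at -0.43 ± 0.28. Cholesterol synthesis genes split into 8 higher and 7 lower of 17 (median -0.093), with TM7SF2 at 0.72 ± 0.15 and INSIG1, a brake on sterol synthesis, at -0.62 ± 0.17. Fatty acid synthesis genes had 3 higher and 2 lower of 11 (median -0.054), with the elongase ELOVL6 at -0.50 ± 0.30. MYC and ribosome biogenesis genes had 5 higher and 6 lower of 16, with a median of -0.051 but a mean of 0.025 and an upward test, from RRP12 at 0.59 ± 0.23 to NOP58 at -0.56 ± 0.25. The values of RFC4, BNIP3, DDIT4, ASNS, RRP12 and NOP58 moved by over 1.5 times when 1 ETV1 array was left out.

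Signalling lists were divided. The Hippo components had 6 higher and 8 lower of 19 with both hairpins (median -0.063), and the transcriptional coactivator YAP1 read 9.87 in the control and 9.22 and 8.81 with ETV1 shRNA (-0.85 ± 0.33). YAP/TAZ-TEAD targets had 6 higher and 3 lower of 12, with a median of 0.015 and a downward test, the angiomotin-like AMOTL2 standing at 0.27 ± 0.15. Invasion and ETS-associated genes had 5 higher and 5 lower of 12, with a median of 0.045, a mean of -0.084 and a downward test, and besides MMP7 the integrin ITGA6 stood at -0.73 ± 0.22. MAPK output genes had 3 higher and 8 lower of 14 (median -0.10), with the feedback inhibitor SPRY1 at -0.65 ± 0.20. Histone lysine demethylases had 5 higher and 5 lower of 17, with a median of 0.0024, a mean of -0.00037 and a downward test, KDM3A standing at -0.46 ± 0.22 and KDM6B at 0.42 ± 0.15. P53 targets had 9 higher and 4 lower of 20 (median 0.099), with the apoptosis gene BAX at 0.35 ± 0.16. Interferon-stimulated genes had 10 higher and 3 lower of 21 (median 0.030), with the ubiquitin-like ISG15 at 0.61 ± 0.14. NF-kB targets had 4 higher and 1 lower of 6 (median 0.067), mesenchymal markers 4 higher and 3 lower of 9 (median 0.030), and neuroendocrine genes 3 higher and 1 lower of 4 (median 0.25), among them the neuronal tubulin TUBB3 at 0.78 ± 0.24 (0.51 to 1.05 by hairpin). Housekeeping genes had 3 higher and 4 lower of 11 (median -0.0069), with the purine salvage gene HPRT1 at -0.82 ± 0.24.

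The comparison of JMJD2A shRNA with the control asked which mRNAs changed when this demethylase was targeted, and 0 genes passed. Values below the control included -1.29 ± 0.19 for CLDND1, a claudin-like membrane protein (control 9.79, JMJD2A shRNAs 8.69 and 8.30, n = 2 against 1), -1.20 ± 0.30 for TMED5 of early secretory transport, and -1.11 ± 0.22 for PRKACB, a catalytic subunit of protein kinase A, whose 3 other probes also lay lower. Further values were -1.06 ± 0.17 for the lipid droplet gene PLIN5, -0.97 ± 0.19 for the membrane-type metalloproteinase MMP16 (its other probe gave -0.12) and -0.89 ± 0.14 for methionine synthase MTR. YAP1 read 9.23 and 8.42 with the JMJD2A shRNAs, a difference of -1.05 ± 0.33 (limma adjusted p = 0.590). Above the control stood GPAA1 of glycolipid anchor attachment (1.10 ± 0.17), PMEPA1, an inhibitor of TGF-beta signalling (1.09 ± 0.17), the cardiac mesoderm factor MESP1 (0.85 ± 0.14) and the differentiation factor CEBPA (0.79 ± 0.16), which read 10.10 with both hairpins and 9.31 in the control. STYX, a pseudophosphatase, stood at -1.34 ± 0.15 on the probe with the higher signal, but its other probe gave 0.06, so its value is uncertain.

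With limma, 0 of 22600 probes passed, the smallest adjusted p being 0.547, and 1678 had an unadjusted p under 0.05 (888 higher, 790 lower) against 1130 expected by chance. The count was also 0 under each alternative run for this comparison, including the intensity trend, no filter and each array left out. On simulated data for this comparison 28.9% of probes changed 2-fold and 89.4% of those changed 3-fold were recovered, and 5.25 unchanged probes passed on average. These rates too hold for 200 changed probes on independent arrays of equal spread, and would be lower where few probes change.

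The cell-cycle lists had unlike medians with the JMJD2A hairpins, a difference that was not tested, with 1 array each. G2/M genes had 13 of 26 lower and 4 higher with both, and a median of -0.095 that was -0.25 with shRNA 3 and 0.015 with shRNA 5. Their largest values were HMMR at -0.63 ± 0.26, NEK2 at -0.49 ± 0.22 and the mitotic kinase CDK1 at -0.46 ± 0.16 (camera adjusted p = 0.175 for the list), where NEK2 ranged from -0.75 to -0.23 by hairpin. DNA replication genes had 8 of 28 higher and 6 lower with both, and a median of 0.051 (-0.093 with shRNA 3 and 0.25 with shRNA 5), with cyclin CCNE1 at 0.56 ± 0.18. ER stress genes had 5 of 16 higher and 3 lower, with a median of -0.0097, a mean of 0.019 and an upward test. The other lists also did not pass, and all 19 described had camera adjusted p from 0.175 to 0.986. Across them 0 members passed in limma over all probes, and 0 when adjusted over the list alone, with at most 6 in a list at an unadjusted p under 0.05.

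The lipid synthesis lists had medians under 0 when the JMJD2A hairpins were averaged, without passing. Cholesterol synthesis genes had 9 of 17 lower and 5 higher with both hairpins (median -0.068), with INSIG1 at -0.64 ± 0.17, the epoxidase SQLE at -0.55 ± 0.17 and the synthase HMGCS1 at -0.52 ± 0.19. Fatty acid synthesis genes had 4 of 11 lower and 2 higher (median -0.11, with 0.046 for shRNA 3 and -0.13 for shRNA 5), with the citrate lyase ACLY at -0.40 ± 0.17. Epithelial genes had 6 of 12 higher and 4 lower (median 0.056), with KRT18 at 0.58 ± 0.15 and KRT19 at 0.48 ± 0.17. Hypoxia and glycolysis genes had 11 of 22 lower and 7 higher (median -0.076), from HK2 at -0.66 ± 0.25 to the aldolase ALDOA at 0.57 ± 0.16. The values of ACLY and HK2 moved by over 1.5 times when 1 JMJD2A array was left out.

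Of the 17 histone lysine demethylases, 10 lay lower and 7 higher with both JMJD2A hairpins (median -0.088), with KDM3A at -0.57 ± 0.22 and KDM6B at 0.56 ± 0.15. Such agreement comes in part from the shared control array. Across all probes the differences with the JMJD2A hairpins had r of 0.597, where simulations of independent unchanged arrays gave 0.502. Hippo components had 6 higher and 7 lower of 19 (median -0.0060), with the kinase TAOK2 at 0.47 ± 0.14. YAP/TAZ-TEAD targets had 4 higher and 2 lower of 12, with a median of -0.0085, a mean of 0.0048 and a downward test. Invasion and ETS-associated genes had 6 higher and 3 lower of 12 (median 0.064), where the mesenchymal factor TWIST1 stood at 0.50 ± 0.23. MAPK output genes had 5 higher and 5 lower of 14, with a median of 0.022, a mean of -0.023 and a downward test, with the transcription factor MYC at -0.35 ± 0.24 and cyclin CCND1 at 0.35 ± 0.25. Both came mostly from shRNA 5, with MYC at -0.065 and -0.63 and CCND1 at 0.047 and 0.64 with shRNAs 3 and 5, and KDM3A and TWIST1 also moved by over 1.5 times when 1 JMJD2A array was left out. P53 targets had 8 higher and 3 lower of 20 (median 0.055), with BAX at 0.45 ± 0.16. Interferon-stimulated genes had 7 higher and 7 lower of 21, with a median of -0.027, a mean of 0.015 and an upward test, ISG15 standing at 0.53 ± 0.14. MYC and ribosome biogenesis genes had 5 higher and 6 lower of 16 (median -0.029), NF-kB targets 3 higher and 0 lower of 6 (median 0.090), mesenchymal markers 2 higher and 2 lower of 9 (median 0.029), and neuroendocrine genes 3 higher and 0 lower of 4 (median 0.18). Housekeeping genes had 6 higher and 1 lower of 11 (median 0.094). The 14-3-3 gene YWHAZ stood at -0.57 ± 0.40, which came from JMJD2A shRNA 5 (11.12, against 12.23 to 12.28 on the other arrays), and without that array the difference was 0.001.

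**Figure D2:**
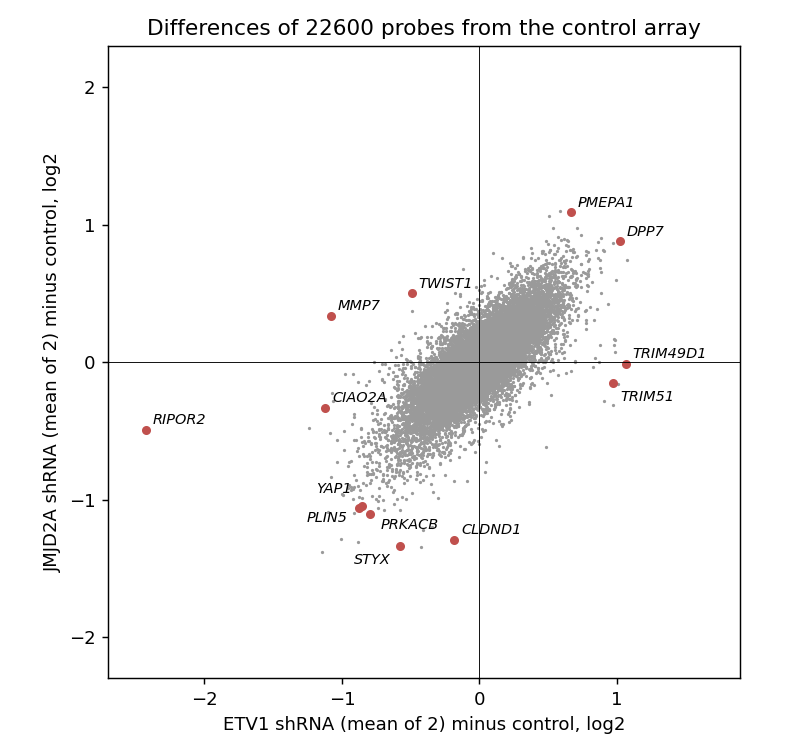
Mean log2 difference from the control array with JMJD2A shRNA (vertical axis) against that with ETV1 shRNA (horizontal axis), with 1 point per tested probe (22600) and some genes labelled. RIPOR2 lies farthest to the left at -2.43, and the cloud follows the diagonal with r of 0.776, where simulations of independent unchanged arrays with a shared control gave 0.667.

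The direct comparison of ETV1 with JMJD2A shRNA asked where the knockdowns differed, without the control array. RIPOR2 fell by 1.94 ± 0.13 with ETV1 relative to JMJD2A shRNA (SE, n = 2 against 2), a 3.83-fold lower signal, with both ETV1 arrays under both JMJD2A arrays. MMP7 was at least 2.44-fold lower on its brighter probe, at -1.42 ± 0.15 (limma adjusted p = 0.389), since it lay under the floor with both ETV1 shRNAs and read 8.15 and 7.79 with the JMJD2A shRNAs, and its other probe gave -0.86. Other values below were TWIST1 at -0.99 ± 0.19, PKIB, an inhibitor of protein kinase A, at -0.83 ± 0.14, the growth hormone receptor GHR at -0.73 ± 0.11 and the apoptosis regulator TNFAIP8 at -0.73 ± 0.14. Above stood CLDND1 at 1.11 ± 0.15 (other probe 0.93), the death receptor TNFRSF21 at 0.84 ± 0.12 and the related receptor TNFRSF19 at 0.71 ± 0.11, whose 2 other probes also lay higher. TRIM48 (1.29 ± 0.18), TRIM51 (1.12 ± 0.14) and TRIM49D1 (1.08 ± 0.12) were also higher in value, with the uncertainty of near-identical copies.

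With limma, 1 of 22600 probes passed, that of RIPOR2 (adjusted p = 0.0359), and 714 had an unadjusted p under 0.05 (342 higher, 372 lower), with 1130 expected by chance. That count lay on either side of the chance number when 1 array was left out, from 541 without ETV1 shRNA 5 to 1785 without ETV1 shRNA 1. On simulated data for this comparison 67.5% of probes changed 2-fold and 95.8% of those changed 3-fold were recovered, and 7.7 unchanged probes passed on average. Here too the rates hold for 200 changed probes on independent arrays of equal spread, and would be lower where few probes change. The RIPOR2 call was lost without the filter (0.225), with the floor on all 5 arrays (0.0633) and without the arrays of ETV1 shRNA 1 (0.553), ETV1 shRNA 5 (0.554) or JMJD2A shRNA 5 (0.0933), in a range of 4.01e-05 to 0.554, while the difference stayed between -1.83 and -1.96 in these settings. MMP7 passed with an intensity trend (adjusted p = 4.01e-05, and 0.0132 for its other probe), with background subtraction (0.0175) and with normexp (0.0167), in a range of 4.01e-05 to 1.00 over the alternatives.

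The DNA replication and ER stress lists had medians under 0 with ETV1 relative to JMJD2A shRNA, in calls that depended on the set test and on single arrays. Of 28 DNA replication genes 6 had both ETV1 arrays under both JMJD2A arrays and 0 had them above, while 21 lay lower and 7 higher by the mean (median -0.085), with CCNE1 at -0.52 ± 0.15, the cell-cycle factor E2F1 at -0.45 ± 0.11 and the helicase subunit MCM4 at -0.36 ± 0.14. The list fell in limma's camera test (adjusted p = 0.0165), a call that was lost at adjusted p = 0.965 with an estimated correlation and at 0.977 with fry. Of 16 ER stress and integrated stress response genes 5 had both ETV1 arrays under both JMJD2A arrays and 0 had them above, while 14 lay lower and 2 higher by the mean (median -0.15), with DDIT4 at -0.37 ± 0.16, the transcription factor CEBPB at -0.35 ± 0.20 and the serine synthesis gene PHGDH at -0.30 ± 0.18. With 1 array left out DDIT4 ranged from -0.59 to -0.15, CEBPB from -0.64 to -0.049 and PHGDH from -0.56 to -0.033. This list also fell (adjusted p = 0.0245), and its call was lost at adjusted p = 0.965 with an estimated correlation and at 0.977 with fry. Without the array of JMJD2A shRNA 5 both turned direction (adjusted p = 0.946). Without that of ETV1 shRNA 1 the values were 0.769 for replication and 0.430 for stress genes, and without that of ETV1 shRNA 5 the stress genes had 0.0567. Their call also ended with background subtraction (0.130 for both).

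The 17 other lists described did not pass in the direct comparison (camera adjusted p from 0.184 to 0.957). G2/M genes had 3 of 26 with both ETV1 arrays under both JMJD2A arrays, 1 with them above and 19 lower by the mean (median -0.10, adjusted p = 0.184), with TOP2A at -0.49 ± 0.26. Housekeeping genes had 4 of 11 with both arrays under, 0 with them above and 8 lower by the mean (median -0.17), with HPRT1 at -0.65 ± 0.19. With 1 array left out TOP2A ranged from -0.83 to -0.15 and HPRT1 from -0.92 to -0.39. The medians were -0.026 for Hippo components, -0.081 for MAPK output, 0.062 for demethylases, -0.058 for p53 targets, 0.045 for interferon-stimulated genes, 0.023 for cholesterol synthesis, -0.055 for hypoxia and glycolysis, 0.00039 for epithelial genes, 0.028 for neuroendocrine genes and -0.052 for NF-kB targets. Lists whose median, mean and test differed in sign were YAP/TAZ-TEAD targets (median 0.018, mean -0.0048, upward test), invasion genes (0.018, -0.13, downward), fatty acid synthesis (-0.0038, 0.025, upward), mesenchymal markers (0.00054, -0.012, upward) and MYC and ribosome biogenesis (-0.0082, 0.039, upward). Over all probes 0 list members passed in limma, and those that passed when adjusted over the list alone were MMP7 (adjusted p = 0.000438) and TWIST1 (0.00773 in the invasion list and 0.0116 in the mesenchymal list).

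**Figure D3:**
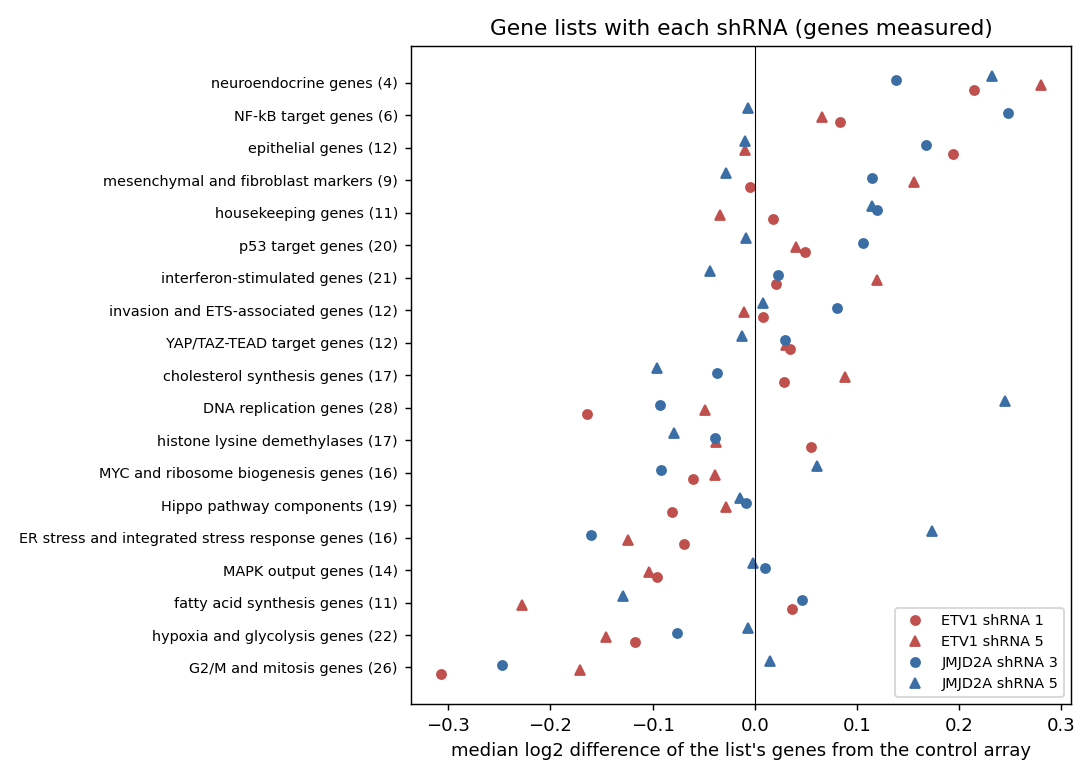
Median log2 difference from the control array (horizontal axis) of the measured genes of each of 19 lists, with 1 point per shRNA array and the number of genes in parentheses. The G2/M list lies at -0.31 and -0.17 with the ETV1 shRNAs, and the DNA replication list lies at 0.25 with JMJD2A shRNA 5 against -0.09 with JMJD2A shRNA 3.

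Genes that moved alike with all hairpins were compared by size. Both ETV1 shRNAs gave a difference of at least 1.5-fold in a shared direction for 233 probes (99 higher, 134 lower), where simulations of independent unchanged arrays of equal spread gave a mean of 172 and at most 195. Both JMJD2A shRNAs did so for 258 probes (108 higher, 150 lower), where simulations gave a mean of 173 and at most 204. All 4 hairpins did so for 72 probes (28 higher, 44 lower), against a simulated mean of 47.9 and at most 66. The arrays do not meet that assumption, since across probes the differences within the targets correlated with each other (r = 0.229), so an excess over these simulations is not shown to exceed chance. With the background mode subtracted the counts were 1416 for ETV1 and 1328 for JMJD2A shRNA. YAP1 was among those lower with all 4, as were PLIN5 and the glucuronosyltransferases UGT2B10 and UGT2B28, while DPP7, the ubiquitin ligase MGRN1 and PMEPA1 were among those higher. In limma 0 probes passed in both knockdowns, with 1871 and 1678 at an unadjusted p under 0.05, and the count was 0 under each alternative run. Across probes, which are not independent replicates, the differences from the control had r of 0.776 and a covariance of 0.0420, where the simulated values were 0.667 and 0.0301, leaving a covariance difference of 0.0119. The same sign occurred in 76.7% of probes, against 73.2% in simulations. The single control array cannot be split, so part of the excess may come from it.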

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

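The tests on RIPOR2 in this part were chosen only after its result was seen. No group had the 4 samples needed to test for a single deviating array.

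RIPOR2 differed between the knockdowns, at -1.94 log2 units with ETV1 relative to JMJD2A shRNA, which is what marked it for a closer look. The direct comparison that gave this difference (limma adjusted p = 0.0359) does not use the control array, so the difference does not rest on the control. Its p-value is what marked the gene, so it is no separate test of a deviating control. The signal was low with both ETV1 hairpins, with a gap of 1.80 log2 units between the higher ETV1 array (7.23) and the lowest of the other 3 (9.03). The call takes its error from the spread between hairpins of a target, so a probe low with only 1 hairpin could hardly have passed. This gap is therefore no separate test of an effect of only 1 of the hairpins. Without either ETV1 array the direct call was lost (adjusted p = 0.553 and 0.554) while the difference stayed at -1.91 and -1.96. A lower RIPOR2 mRNA after ETV1 knockdown may be proposed only as a hypothesis. The deposited values held no other RIPOR2 probe to show that this probe reads RIPOR2 mRNA alone, and the ETV1 probe read at background.

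The DNA replication list was marked because it differed between ETV1 and JMJD2A shRNA, with a median of -0.085, and the ER stress and integrated stress response list because of its median of -0.15. CCNE1 and E2F1 in the former and DDIT4 and CEBPB in the latter had the largest values. The medians from the control with JMJD2A shRNAs 3 and 5 were -0.093 and 0.25 for replication genes and -0.16 and 0.17 for stress genes. Without the array of JMJD2A shRNA 5 both differences changed direction. With ETV1 shRNAs 1 and 5 the medians from the control were -0.16 and -0.048 for replication genes and -0.070 and -0.12 for stress genes. Among the shRNA arrays only JMJD2A shRNA 5 had medians above 0 for these lists. The direction of both differences therefore rests on that array. Both calls were also lost without the array of ETV1 shRNA 1, and that of the stress genes without ETV1 shRNA 5. Those fits hold 1 ETV1 array, so these losses do not show that other arrays carry the calls. Neither list passed in camera with an estimated correlation (adjusted p = 0.965) or with fry (adjusted p = 0.977). Housekeeping genes had a median of -0.17 in the same comparison, with 8 of 11 lower by the mean, though that list did not pass. Medians of this size were therefore not particular to the flagged lists. No biological explanation was tested for these differences.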

How the results depend on the processing

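The subtraction of the background mode, normexp on the deposited values and the floor on all 5 arrays were chosen only after the data were seen; the other alternatives were set beforehand. Of 1800 alternative values for 177 results, 1742 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. Of the rest, 21 were weaker, 4 stronger, 8 reversed and 25 moved. For single genes and lists these labels do not take the size of a change into account. Many of these values could hardly change their label. Part of the genes were chosen because both hairpins moved alike, and most values started far from the threshold. The trend and the omitted filter leave a gene's difference as it was. The number kept is therefore no measure of robustness. The count for JMJD2A shRNA against control and the count called in both knockdowns were 0 under each alternative run, and the targets kept their sign (ETV1 from -0.21 to -0.20 and KDM4A from -0.35 to -0.15, each with its own shRNA, arrays left out in turn, and -0.74 and -0.82 with subtraction). The counts for ETV1 shRNA against control and for the direct comparison, 1 each, became 0 with no filter, which tests more probes, 0 with the floor on all 5 arrays, and 3 with an intensity trend. The direct count was 2 with subtraction, where MMP7 joined RIPOR2, and 2 with normexp. The gene lists that passed, 3 in all, became 1 with subtraction, 0 with an estimated correlation and 0 with fry. The G2/M list with ETV1 shRNA had adjusted p of 0.965 and 0.977 with these last settings, as had the DNA replication and ER stress lists in the direct comparison, which had 0.130 with subtraction. Subtraction widened folds near background, and the probes at least 1.5-fold apart with both hairpins became 1416 for ETV1 and 1328 for JMJD2A. With arrays left out in turn, the counts ranged from 0 to 1 (ETV1 shRNA against control), 0 to 1 (direct) and 0 to 6 (gene lists), and the adjusted p from 3.24e-05 to 0.430 (G2/M), 4.71e-07 to 0.946 (DNA replication) and 1.58e-06 to 0.946 (ER stress), the last pair reversed without JMJD2A shRNA 5. Differences that changed sign were ETV1 with JMJD2A shRNA (-0.054 to 0.080), KDM4A with ETV1 shRNA (-0.12 to 0.17), YAP1 in the direct comparison (-0.21 to 0.59, also -0.011), and YWHAZ with JMJD2A shRNA (-1.14 to 0.00097) and in the direct comparison (-0.0079 to 1.14). Of 164 values of single genes, 47 moved by over 1.5 times with an array left out. Leaving out an array of a pair leaves 1 array, assumed to vary like the others; where no construction is named, the cause was not tested. No paired analysis was possible because the groups share only 1 shRNA number, which names different constructs. Counts with both hairpins have no value with an array left out, and the trend and averaged probes gave none for gene lists. Alternatives set beforehand on the unnormalized signals or detection p were not run. Background within the deposited signals limits folds of genes near the floor, the targets among them.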

Other observations

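The tests of a factor shared by arrays and of knockdown strength were chosen only after the result was seen, as were the genes named in the next paragraphs and the reason given for setting aside the simulated limit of 66. A test of whether the probes of TRIM49 copies read a single transcript was dropped after its result was seen, because a probe at the floor and the unsubtracted background made it void, and nothing is drawn from it.

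Some genes stood apart on single arrays. With JMJD2A shRNA 5 SNAR-A1, a small noncoding RNA with near-identical copies, read 10.88 against 12.34 to 13.05 elsewhere, and BCYRN1, a neuronal noncoding RNA, read 10.36 against 11.71 to 12.12. The choline transporter SLC44A1 read 8.45 there, against 9.77 to 10.33, and the DNA glycosylase TDG 9.67, against 10.77 to 10.79. With ETV1 shRNA 5 DAZAP2 read 10.31 against 11.34 to 11.71, and the chaperonin subunit CCT6A 9.49 against 10.39 to 10.70. With JMJD2A shRNA 3 DDC, the dopa decarboxylase, read 9.81 against 10.68 to 11.70. These have no replicate check.

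The probes at least 1.5-fold apart from the control with all 4 hairpins numbered 72, and included OTUB1, a deubiquitinase (0.78 with ETV1 and 0.81 with JMJD2A shRNA), the condensin gene SMC2 (-0.82 and -0.73) and the AMP-activated kinase gene PRKAA1 (-0.80 and -0.68). Simulations of independent unchanged arrays of equal spread gave at most 66. The prediction made beforehand, that a count above these simulations would speak against chance, needs arrays that vary alike, whereas the shRNA arrays stood equally far beyond the other 4 for 7 to 91 probes, by an unequal spread or by effects of single hairpins, which were not separated. The count of 91, with JMJD2A shRNA 5, is consistent with a single array standing apart to this extent, so chance in the control stays open. A response to either knockdown or to any active hairpin stays open and cannot be told apart from a control culture that differed, with 1 control array.

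The arrays of ETV1 shRNA 1 and JMJD2A shRNA 3 were closer to each other than the arrays of either target. A few probes with large differences as the cause are argued against by the median absolute difference, which was 0.811 of the smaller value within a target. Across probes, the difference between the ETV1 arrays correlated with that between the JMJD2A arrays (r = 0.229, Spearman 0.203, probes not being independent replicates). This r follows from the same distances between arrays that make up the pattern, so it is no separate support for a shared factor. A factor shared by pairs of arrays, such as handling or growth, stays open. Unequal knockdown stays open. KDM4A lay at -0.20 with shRNA 5 relative to shRNA 3, near the floor and from 1 array each, without an error of its own. ETV1 was under the floor on both of its arrays.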
